A study of Mus musculus and Rattus norvegicus with 43 samples.

How the data were processed

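The study measured gene expression by RNA sequencing in the striatum of a single hemisphere of C57BL/6 mice and Sprague Dawley rats aged 4 months. The animals had been injected on postnatal day 0 with a control miRNA, a miRNA against both the C-TAF and N-TAF forms of Taf1 (labelled C/N-TAF miRNA, here CN) or a miRNA labelled N-TAF miRNA (here N). Taf1 encodes the largest subunit of the general transcription factor TFIID, and N-TAF is its neuronal isoform. Tissue was frozen, RNA was taken with Trizol and libraries were sequenced on an Illumina instrument, per the labels' protocols.

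Raw read counts per Ensembl gene were deposited, with 1 table per species and 1 column per animal. Mouse reads were aligned with STAR and rat reads with HISAT2, and both were counted with featureCounts, per the submitters' processing notes, which also name edgeR and give no versions. Those notes name a human build, GRCh38, for the mouse libraries, while the rows of the mouse table carry mouse gene identifiers. The build is therefore unsettled and no coordinates are printed. The annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. Counts are per gene and do not separate the isoforms of Taf1.

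The mouse table held 54532 gene rows, of which 54409 matched a symbol in the reference table of gene names, and the 123 others took 0.07% of the counts. The rat table held 32883 rows. No table used here pairs rat identifiers with names, so rat genes are given by identifier only, and Taf1, the gene lists, the sex class and a comparison of mouse with rat were not analysed in rat. Groups were taken from the injection label. They comprised 8 control, 5 CN and 8 N mice and 5 control, 8 CN and 8 N rats. For 1 mouse that label names no injection, and this library entered no comparison. Replicates were numbered within groups in the order of the records, so numbers do not pair animals. The closest pair of libraries within any group differed by 5.913 times sampling noise (chi-square per degree of freedom over genes with at least 20 counts in the pair), so no library was counted as a duplicate.

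All fits used the deposited counts as they stand. For each species the 3 groups entered a single edgeR quasi-likelihood fit (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust dispersion, TMM scaling and the filterByExpr filter. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM (read counts scaled to a common library total). In mouse, 36 gene lists (classes of striatal neurons, glia, vessels and neighbouring tissues, synaptic genes, stress and immune responses, and housekeeping complexes) were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation. A list score per library is the mean over members of the log2 CPM after subtraction of the control mean. An exact two-sided permutation test of these scores, with Benjamini-Hochberg adjustment over the 36 lists of a comparison, was run beside it.

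Groups, lists, tests and the rule for named genes were fixed before the data were examined. The rule names Taf1, the 10 genes that rose most and the 10 that fell most among called genes with a usual symbol and a mean of at least 1 CPM (5 each for CN against N), the 3 genes of smallest p in each direction where none was called (2 by identifier in rat), and up to 4 members of smallest p per list described. A few genes that the rule takes are not reported here. Its use on the fit without CN library 2 was decided after seeing the data, since that library stands apart from the other mouse libraries.

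Other settings fixed beforehand were RLE scaling, no filter, a stricter filter, only the 2 groups compared, sex class from Xist against Y-linked counts, the first surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma-voom and leaving out each library in turn. After seeing the data, the class of a library by reads of Ambn (above or below 0.5 CPM) was added as a covariate and as a split, as were fits without CN library 2 combined with other settings, a fit without CN libraries 1 and 2 and, in rat, the range of the animal numbers. Ambn encodes an enamel matrix protein. Among libraries of the compared groups it stood at 2.03 CPM or more in the first class and at 0.0758 or less in the other, while the library without a stated injection had 1.1. The exact test of list scores also counts among the alternatives added after seeing the data.

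Library totals were 24.9 to 35.6 M (mega) counts in mouse and 19.2 to 32.9 M in rat. The median standard error of a log2 fold change for mouse genes at 10 CPM or more was 0.092 for CN against control and 0.0808 for N against control. The procedure was tested on simulated counts with 200 changed genes. At 1.5-fold it recovered 59.7% of them for mouse CN against control (19180 genes), 83.6% for N against control (19214 genes) and 74.6% for CN against N (19164 genes), and for the same comparisons in rat 73.1%, 68.7% and 67.2% (15854, 15864 and 15852 genes). At 2-fold it recovered 91%, 92.5% and 98.5% in mouse and 88.1%, 85.1% and 89.6% in rat. The simulated genes varied independently, the 200 changed genes had at least 1 CPM, and no library differed by transcript length or by RNA of another tissue. These shares need not hold for the real libraries, and a count of 0 genes called is not evidence of no change. Transcript length and GC content came from the longest coding transcript of a gene in the mouse reference annotation and were used only to compare libraries.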

Results

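Striatal RNA was sequenced from 22 mice and 21 rats at 4 months of age, after injection on postnatal day 0 of a control miRNA, a miRNA against both Taf1 forms (CN) or a miRNA against the N-TAF form (N). Library totals were 29.5 ± 3.27 M counts in 8 control mice, 32.3 ± 3.46 M in 5 CN mice and 28.3 ± 2.32 M in 8 N mice (mean ± SD). In rat they were 22.8 ± 2.79 M in 5 controls, 23.5 ± 4.69 M in 8 CN and 22.0 ± 2.11 M in 8 N animals. The mouse without a stated injection had 25.5 M counts. The design asks how expression in the striatum differs from the control after each miRNA, and groups are named by the injection their labels give. Each column is a separate animal by its label. The p-values for single genes and of the exact permutation test measure the spread between these animals. Those of camera with the preset correlation do not, since they treat the genes of a list as nearly independent. For cholinergic and endothelial genes the estimated correlation was 0.316 and 0.297. For N against control camera gave them unadjusted p-values of 3.18e-11 and 1.46e-16, and the exact permutation test 0.000777 and 0.000622.

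Taf1 (ENSMUSG00000031314), the targeted gene, was at 98.6 ± 5.53 CPM in control mice (SD, n = 8), 90.7 ± 22.6 in CN (n = 5) and 97.5 ± 6.19 in N (n = 8). The log2 fold change was -0.12 (SE 0.113, adjusted p = 0.703 by edgeR) for CN and -0.016 (SE 0.0986, adjusted p = 0.987) for N. Neither differed from the control by more than the spread between animals. The lower CN mean came from CN library 2 at 50.6 CPM, while the 4 others lay between 95.7 and 105, and without it the CN value was 0.035. That library differed from all others in its dependence on transcript length, and CN library 1 had the highest value in the other direction (rho 0.561, next 0.333). Gene counts add all Taf1 transcripts, so the level of the N-TAF form alone was not measured here. No lower Taf1 was thus shown in either group, and the directions below are those of the labelled groups.

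**Figure D1:**
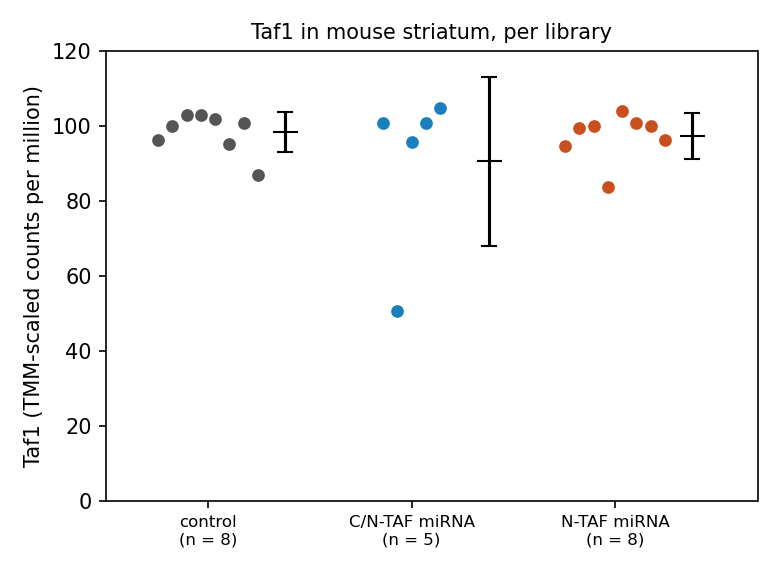
Taf1 level per mouse library in TMM-scaled CPM (vertical axis) by injected miRNA (horizontal axis); points are libraries, and the bar beside each group is its mean ± SD. The 8 N libraries lie between 83.7 and 104 CPM and the 8 controls between 87.1 and 103, while a single CN library stands at 50.6.

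**Figure D2:**
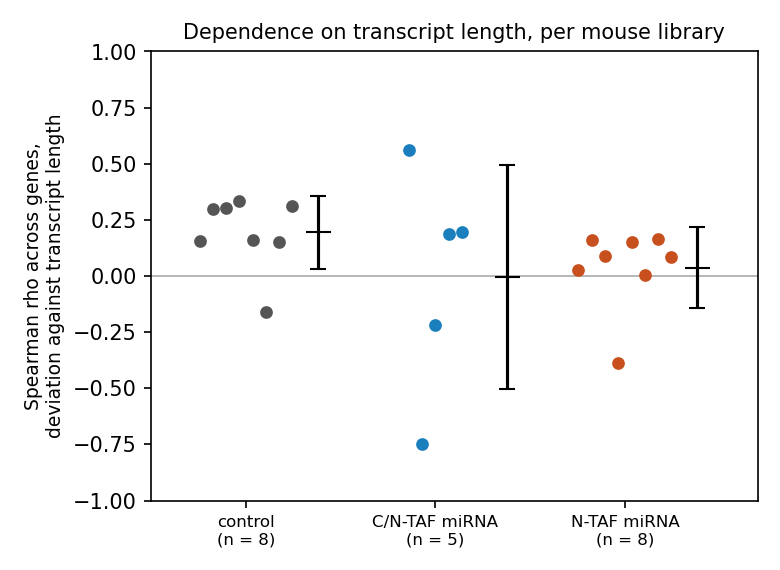
Spearman rho across genes between a library's deviation from the mean of the other mouse libraries and transcript length (vertical axis) by injected miRNA (horizontal axis); points are libraries, and the bar beside each group is its mean ± SD. CN library 2 lies at -0.75, while the others lie between -0.386 and 0.561.

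Mice given the N miRNA were compared with controls to see what differs in the group labelled as given the miRNA against the N-TAF form. Markers of cholinergic interneurons and of blood vessels fell as groups in the N libraries, with smaller decreases in genes of spiny projection neurons. Genes of newborn neurons rose, and whether that rise lies in the striatum or in neighbouring tissue was not tested. Of 12 cholinergic markers, 7 fell when adjusted over the list alone and 5 did not pass, and 0 passed over all genes tested. Those that fell included Ecel1 at -0.45 (SE 0.095), Slc10a4 at -0.43 (SE 0.1) and Slc17a8, the vesicular glutamate transporter of these cells, at -0.52 (SE 0.129). Slc5a7 (-0.56), Slc18a3 (-0.42) and Chat (-0.42), which carry choline uptake, acetylcholine loading and acetylcholine synthesis, were among the 7. The list median was -0.40, and camera with the preset correlation gave an adjusted p of 5.73e-10 (adjusted p = 0.060 with an estimated correlation, and 0.291 without CN library 2). The list score was lower than the control mean in 8 of 8 N libraries and below every control in 7, by -0.31 on average (adjusted p = 0.014, exact permutation test).

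Of 15 endothelial and mural genes, 11 fell when adjusted over the list alone, 4 did not pass and 0 passed over all genes. Slco1a4, an organic anion transporter of the blood-brain barrier, was at -0.42 (SE 0.0851), Rgs5, a pericyte gene, at -0.41 (SE 0.088), and the VEGF receptors Flt1 and Kdr at -0.54 (SE 0.12) and -0.46 (SE 0.118). The list median was -0.33 (adjusted p = 5.27e-15 by camera; adjusted p = 0.039 with an estimated correlation, a call lost without CN library 2 at adjusted p = 0.209), and the score was below the control mean in 8 of 8 N libraries (difference -0.35, adjusted p = 0.014, exact permutation test).

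Of 20 genes common to spiny projection neurons, 7 fell over the list alone (13 without CN library 2) and 0 over all genes, among them Rgs9 (-0.24), Rasd2 (-0.21) and Actn2 (-0.19). The list median was -0.14, and the call was lost with the other correlation (adjusted p = 0.248 with an estimated correlation). Among 8 direct-pathway genes, Slc35d3 (-0.36), Drd1 (-0.20) and Chrm4 (-0.27) fell over the list alone and Pdyn, the dynorphin precursor, rose (0.24), with a list median of -0.13 (adjusted p = 0.060 with an estimated correlation). Of 13 neurogenesis genes, 6 rose over the list alone, 7 did not pass and 0 passed over all genes. Dlx1 was at 0.60, Sox11 at 0.51, Dcx, a microtubule protein of migrating neuroblasts, at 0.62 and Dlx2 at 0.53. The median was 0.44 (adjusted p = 6.65e-08 by camera; adjusted p = 0.135 with an estimated correlation). In the exact permutation test of scores, 9 of 36 lists passed for N against control. Besides the 5 lists above, scores of dystonia genes (-0.085) and oligodendrocyte precursors (-0.086) were lower, while those of other interneurons (0.20) and muscarinic and nicotinic receptors (0.23) were higher. Camera called the first pair too (medians -0.091 and -0.078; adjusted p = 0.225 for both with an estimated correlation), but in 16 and 12 of 21 refits with a library left out it did not, and the dystonia median was -0.044 without N library 1. Camera did not call the interneuron and receptor lists (adjusted p = 0.0673 and 0.276). Immediate-early genes (median -0.48, with Npas4 at -0.82 and Egr4 at -0.58 lower over the list alone) and microglial genes (median -0.093, 0 of 16 passing) were called by camera and not by the score test (adjusted p = 0.392 and 0.368 with an estimated correlation). With CN library 2 left out 0 of the immediate-early and 2 of the microglial genes passed over the list alone. Camera also called channels (-0.065) and oligodendrocytes (-0.079) downwards and oxidative phosphorylation (0.091) upwards (adjusted p = 0.788 for each with an estimated correlation). Of their members 1 channel gene fell over the list alone, and 8 fell without CN library 2. The first 2 calls were lost in 13 of 21 refits with a library left out, and the oligodendrocyte median was 0.00070 without N library 5. Dependence on transcript length ranged from rho -0.386 to 0.165 in N libraries and from -0.161 to 0.333 in controls. Its part in the channel, oligodendrocyte and oxidative phosphorylation calls was not tested. Calb2 (1.26) and Htr3a (0.66) rose among the interneuron genes and Chrm5 (1.11) among the receptors, each over the list alone.

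**Figure D3:**
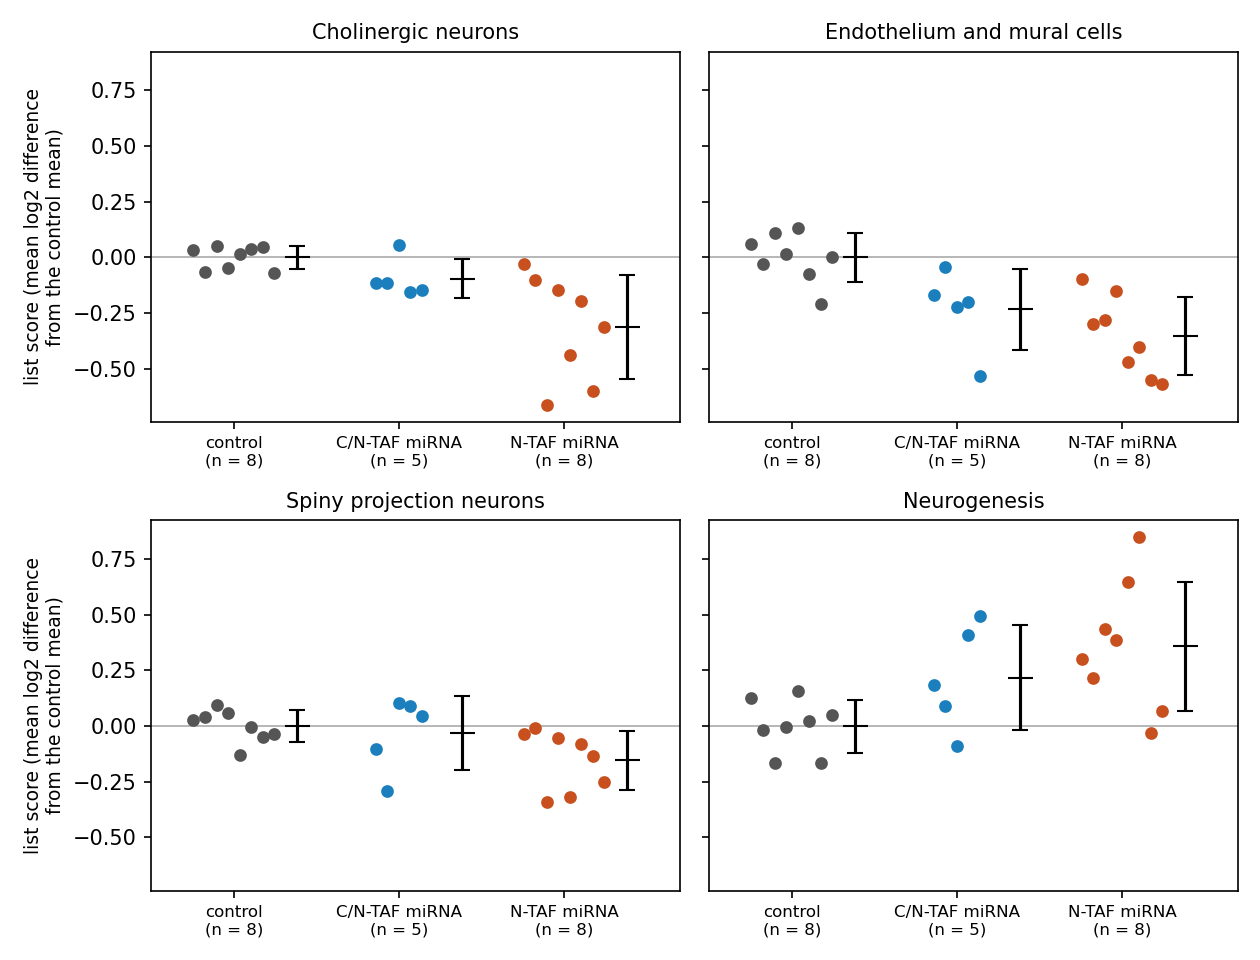
List score per mouse library (vertical axis, mean log2 difference from the control mean) by injected miRNA (horizontal axis) for 4 gene lists; points are libraries, and the bar beside each group is its mean ± SD. N libraries lie below 0 for cholinergic, endothelial and spiny neuron genes in 8 of 8 cases, and above it for neurogenesis genes in 7 of 8.

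Markers of neighbouring tissue moved with some N libraries. The choroid plexus list had a median of 1.09 and ependymal genes 0.37, both called by camera with no member passing over the list alone (adjusted p = 0.788 for both with an estimated correlation). Without N library 6 the medians were 0.32 and 0.17 and neither was called, and with each library left out the calls were lost in 14 and 4 of 21 refits. Cortical and hippocampal excitatory genes, at a median of 0.32 with 0 of 12 members passing, were called as well (adjusted p = 0.788 with an estimated correlation), and their median was 0.075 without N library 7. Ttr, the main choroid plexus transcript, reached 1586 and 3413 CPM in N libraries 5 and 6, while controls went up to 904.7. Reads of Ambn, an enamel matrix gene, stood at 0.5 CPM or more in 5 of 8 control, 3 of 8 N and 4 of 5 CN libraries. Within these libraries the N medians were -0.23 for cholinergic, -0.32 for endothelial, -0.095 for spiny neuron and 0.19 for neurogenesis genes, and in those below that level -0.50, -0.35, -0.17 and 0.61. The cortical and hippocampal median was 0.86 in the former and -0.17 in the latter, and the choroid plexus median -0.14 and 1.23. Without CN library 2 and the 3 N libraries richest in choroid plexus RNA, the cholinergic, endothelial, spiny neuron and neurogenesis medians were -0.38, -0.30, -0.17 and 0.28. Controls with high Ttr stayed in that fit, and its choroid plexus median was -1.43, so the imbalance in this tissue was turned and not removed. The neurogenesis median was 0.44 with all libraries and 0.33 without N library 6, so part of its size went with libraries rich in choroid plexus RNA.

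Gene by gene, 0 of 19413 genes passed for N against control in the edgeR fit of all libraries. At an unadjusted p under 0.05 there were 1822, where a share of 0.05 of the genes is 971. DESeq2 called 73 genes and limma-voom 0. The smallest p belonged to Slc25a18 (0.83), Sord (0.40) and Gli1 (1.01) upwards and to Kcp (-0.77), Caskin2 (-0.29) and Cxcl12 (-0.66) downwards, with adjusted p between 0.0858 and 0.0872. Without CN library 2, which shares the dispersion estimate with these groups, 197 genes passed, 66 higher and 131 lower. A fit of the N and control libraries alone called 209, of which 162 were among the 197 in the same direction. With CN library 1 left out as well, 300 passed, including 195 of the 197. Other single libraries left out of the whole set gave fewer calls, 11 without CN library 1, 32 without N library 1 and 0 without any other.

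In that fit without CN library 2, Gli1 (ENSMUSG00000025407), the transcriptional effector of hedgehog signalling, rose 2.01-fold from 1.86 ± 0.392 to 3.76 ± 1.26 CPM (SD, n = 8 each; adjusted p = 0.012 by edgeR; higher in 8 of 8 N libraries). Slc25a18 (ENSMUSG00000004902), a mitochondrial glutamate carrier, rose from 13.4 ± 1.82 to 23.7 ± 5.67 CPM and lay above every control in 8 of 8 N libraries (adjusted p = 0.00967). The neuroblast genes Sp8 (log2 fold change 1.29) and Dcx (0.61) also rose, as did Col7a1 (0.94), Cd1d1 (0.82), Crocc2 (0.79), the muscle actin Acta1 (0.72, and 0.60 with all CN libraries but without N library 8), Pafah1b3 (0.71) and Dnhd1 (0.61). N libraries 5 and 8 also held the skeletal muscle transcript Myh4 at 16.1 and 15.7 CPM. Kcp (ENSMUSG00000059022), a modulator of BMP signalling, fell from 1.97 ± 0.265 to 1.15 ± 0.224 CPM, below every control in 8 of 8 N libraries (adjusted p = 0.020). Klf2 (-0.73) and Sox17 (-0.70), transcription factors of endothelium, fell with Zfp366 (-0.72), Cyyr1 (-0.69), the chemokine Cxcl12 (-0.66), Ushbp1 (-0.61), the Notch target Nrarp (-0.57) and Col1a1 (-0.57). Of the lists, 6 cholinergic, 5 endothelial and 2 neurogenesis genes passed over all genes in this fit. With the Ambn class as a covariate 16 of the 197 genes were called, and 40 of them were among the 45 called without the 3 choroid-rich N libraries.

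Mice labelled as given the miRNA against both forms were compared with controls in the same way. Lists of blood vessel and newborn neuron genes were called by camera with medians below and above 0, but not by the exact permutation test of scores (adjusted p = 0.154 and 0.256). The medians of ribosomal and respiratory genes rested on a single library. Of 15 endothelial and mural genes, 5 fell over the list alone and 0 over all genes: Pdgfrb (-0.24), Slco1a4 (-0.35), Kdr (-0.47), Vwf (-0.62) and Flt1 (-0.37). The last 2 did not pass without CN library 2, which left 3. The median was -0.22, and -0.24 without CN library 2 (adjusted p = 0.824 and 0.634 with an estimated correlation). The neurogenesis list had a median of 0.29 with 0 of 13 members passing (adjusted p = 0.824 with an estimated correlation), 0.30 without that library and -0.16 among libraries with Ambn under 0.5 CPM, where CN has a single library. Camera called cytosolic ribosomal proteins at a median of 0.33 and nuclear oxidative phosphorylation at 0.23 with 0 members passing (adjusted p = 0.824 for both with an estimated correlation). The ribosomal score of CN library 2 was 1.26 while the next CN library was at 0.081, and without that library both medians turned to -0.045 and -0.051. Ependymal genes (0.35), immediate-early genes (0.16, from 0.091 without CN library 4 to 0.28 without CN library 2) and choroid plexus genes (0.041, but -0.21 without CN library 5) were also called upwards with 0 members passing (adjusted p = 0.824 for each with an estimated correlation). Of 21 refits with a library left out, 2, 9 and 8 lost these calls. Unfolded protein response genes (0.19 with the library, 0.038 without), channels (-0.16 and -0.032) and glutamate receptors (-0.13 and -0.0089) moved in the same way and had 0 members passing. Cortical and hippocampal excitatory genes were at -0.37 and not called, but were called downwards without CN library 2 (-0.92, adjusted p = 0.876 with an estimated correlation). In either fit 1 of 12 members passed over the list alone. With all libraries camera called 10 lists, and 0 with an estimated correlation or by the exact permutation test of scores.

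For CN against control 0 genes passed in edgeR, DESeq2 and limma-voom, with 1623 at an unadjusted p under 0.05, where a share of 0.05 is 971. The smallest p belonged to Thegl (1.67), Cebpz (0.26) and Gm44242 (2.11, but 0.74 without CN library 2) upwards. Downwards it belonged to Fn1 (-0.63), which encodes fibronectin, Sfrp4 (-0.82), a secreted Wnt antagonist, and Col4a1 (-0.39), a collagen of basement membranes (adjusted p = 0.59 for all 6). Sfrp4 was at 0.697 ± 0.183 CPM in CN and 1.24 ± 0.131 in controls, below every control in 5 of 5 CN libraries. Since Sfrp4 was named for its small p, this position is no separate support. Without CN library 2 there were also 0 calls, with 1146 genes at an unadjusted p under 0.05, and Htr1b, a serotonin receptor gene (0.32), Unc79 (0.20), Ly6e (-0.35) and Sipa1 (-0.35) were among those of smallest p. With all libraries these stood at 0.21, 0.030, -0.0016 and -0.22, and without CN library 1 alone at 0.15, -0.057, 0.060 and -0.15.

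The 2 miRNA groups were set against each other to ask where they differ. The same N libraries enter N against control, so a list that fell there tends to be higher here, which is no separate support. Immediate-early genes and cholinergic and spiny neuron markers had medians above 0 for CN against N and were called by camera, but not by the exact permutation test of scores (adjusted p = 0.196, 0.323 and 0.533). Of 17 immediate-early genes 10 rose over the list alone, including Npas4 (1.04), Egr4 (0.84), Junb (0.72) and Egr1 (0.63), with a median of 0.72 (adjusted p = 0.415 with an estimated correlation). Of 12 cholinergic genes 6 rose, among them Ecel1 (0.49), Slc10a4 (0.45) and Slc18a3 (0.38), with a median of 0.35 (adjusted p = 0.366 with an estimated correlation). Of 20 spiny neuron genes 6 rose (14 without CN library 2), with Arpp21 at 0.23 and Rgs9 at 0.30 (list median 0.13, adjusted p = 0.535 with an estimated correlation; -0.0051 among libraries with Ambn at 0.5 CPM or more). Of 16 microglial genes 5 rose, including P2ry12 (0.27) and Siglech (0.30), with a list median of 0.26 (adjusted p = 0.366 with an estimated correlation), which became 0.07 with 2 members passing without CN library 2. Camera also called ribosomal (0.26), interferon response (0.62), oligodendrocyte (0.17) and endothelial (0.11) genes upwards with 0 members passing, and unfolded protein response genes (0.18) with Hspa5 (0.32), Xbp1 (0.26) and Creld2 (0.32) higher and Sesn2 (-0.37) lower over the list alone. The interferon (0.31), oligodendrocyte (0.071), endothelial (0.093) and unfolded protein response (0.070) lists were not called without CN library 2, and Creld2 did not pass. The endothelial median also ran from 0.052 without CN library 1 to 0.19 without CN library 5, and its call was lost in 8 of 21 refits with a library left out. Ribosomal (-0.10) and oxidative phosphorylation genes (-0.12) were then called downwards with 0 members passing (adjusted p = 0.855 and 0.63 with an estimated correlation). Both calls ended with CN library 1 left out as well (-0.063 and -0.045), a library whose oxidative phosphorylation score was -0.445 while the 3 others lay between -0.023 and 0.12. Direct-pathway genes were higher (0.17, with Slc35d3 at 0.47 and Drd1 at 0.23). Cortical and hippocampal excitatory genes (-0.60, with Neurod1 at -2.69) and channels (-0.067, with Kcnj6 at -1.12) were called downwards. The cortical median was -1.48 without CN library 2 (7 members lower over the list alone, 1 with it), -0.34 without N library 7 and not called without CN library 1 (-0.44), 3 (-0.40) or 4 (-0.42), and that of channels was 0.056 without CN library 2. Each of these calls was lost with an estimated correlation (smallest adjusted p = 0.232 over all lists with an estimated correlation). The choroid plexus list had a median of -1.11, although camera placed it upwards in rank without a call. By the exact permutation test of scores 0 of 36 lists differed between CN and N (smallest adjusted p = 0.0558), so the cholinergic difference of 0.22 between them was not past its threshold (adjusted p = 0.323).

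In the fit of all libraries 0 genes passed for CN against N, with 2294 at an unadjusted p under 0.05. DESeq2 called 162 and limma-voom 0. Gli1 (-1.36), Col7a1 (-1.31) and Gm29156 (-1.24) had the smallest p downwards and P4ha1 (0.45), Dbpht2 (0.40) and Rxrg (0.56) upwards, with adjusted p of 0.0632 to 0.0641. Without CN library 2, 70 genes passed, 51 higher and 19 lower in CN, and 30 of these genes were also among the 197. The 2 comparisons share the 8 N libraries, which raises this overlap, and no expected count was computed for it. Htr1b (ENSMUSG00000049511) stood at 89.8 ± 8.12 CPM in the 4 CN libraries and 62.9 ± 5.27 in the 8 N libraries (log2 fold change 0.51, adjusted p = 0.000655 by edgeR). P4ha1, a collagen prolyl hydroxylase (0.46), Dubr (0.49), Kitl (0.41) and Sik2 (0.41) were also higher in CN, and Gli1 (-1.54), Col7a1 (-1.45), Kcnk4 (-1.03), Pomc (-0.95) and Sfrp4 (-0.94) lower. With all 5 CN libraries Pomc was at -0.21. Without CN library 1 and with CN library 2 kept, values were 0.35 for Htr1b, 0.22 for Dubr, 0.15 for Kitl, 0.015 for Sik2 and -0.0077 for Pomc. With the Ambn class as a covariate 8 of the 70 were called. Leaving out CN library 1 as well, which leaves 3 CN libraries, called 4 genes, all among the 70, namely Htr1b (0.46), Gli1 (-1.58), Rundc1 (0.33) and Mtfp1 (-0.44), the last 2 named after their values were seen.

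The log2 fold changes of CN and N share their controls, which raises any agreement between them. Across 19413 mouse genes the log2 fold changes of CN and N correlated at r = 0.337, where unchanged groups simulated against the same controls gave a median of 0.438. The covariance was 0.0208 beside a simulated 0.0192. With CN library 2 left out, r was 0.242 (simulated 0.414) and the covariance 0.0142 (simulated 0.0167), so the difference turned to -0.00254. With the controls split, each part serving a single miRNA group, r had a median of 0.044. At an unadjusted p under 0.05, 103 genes were higher in both (50 for independent lists, at most 99 in 20 simulations) and 113 lower in both (28 for independent lists, at most 81 in 20 simulations). With another draw of the simulations the highest count upwards lay above the observed one. Genes are not independent replicates, and these values describe the gene sets only.

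In rat, 0 of 16005 genes passed in any comparison in the edgeR fit or by limma-voom. The counts at an unadjusted p under 0.05 were 1442 for CN against control, 634 for N against control and 1123 for CN against N, where a share of 0.05 is 800. DESeq2 called 32 genes for CN against control, 4 higher and 28 lower, 1 for N against control and 0 for CN against N. For CN against control the smallest p belonged to ENSRNOG00000027234 (0.39, SE 0.0786) and ENSRNOG00000007030 (0.32, SE 0.0669) upwards, and to ENSRNOG00000005996 (-0.70, SE 0.126) and ENSRNOG00000033609 (-1.61, SE 0.317) downwards, with adjusted p of 0.183 to 0.216. The gene ENSRNOG00000027234 was at 14.8 ± 0.846 CPM in CN (n = 8), 14.1 ± 1.62 in N (n = 8) and 11.2 ± 0.69 in controls (n = 5), above every control in 8 of 8 animals of either miRNA group, and had an adjusted p of 0.999 for N. It had the smallest p upwards in both comparisons, which share these 5 controls, so its position is no separate support. The fold changes of the 2 rat miRNA groups correlated at r = 0.607 over genes, with a simulated median of 0.633 for unchanged groups and 0.0318 with the controls split. At an unadjusted p under 0.05, 105 genes were higher in both (12 for independent lists, at most 124 in 20 simulations). Lower in both were 145 (16 for independent lists, at most 103 in 20 simulations). The simulated genes varied independently, so these counts describe the gene sets only. Animal numbers above 100 made up 3 of 5 control, 1 of 8 CN and 4 of 8 N rats, and with that range as a covariate 0 genes passed in any rat comparison.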

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

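The tests of the Ambn class, of dilution by another tissue and of a wrong label were chosen after the results were seen, and those of transcript length, GC content and other splits of the samples before.

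CN library 2 stood apart from the other mouse libraries, with a median Spearman correlation of 0.958 to the control libraries. Within its group it was far from the others for Taf1 (50.6 CPM, nearest 95.7) and for the scores of glutamate receptors (-0.5393), channels (-0.7861), the unfolded protein response (0.5882), ribosomal proteins (1.259) and microglia (0.485). Its higher median correlation with the control and N groups was 0.959, where their own libraries had at least 0.988. Its median over all mouse libraries was as low (0.958), and no value against the CN libraries alone is given here. A wrong label therefore cannot be told apart from a correct one. Its deviation followed transcript length across genes (rho -0.75, other libraries -0.386 to 0.561; -0.728 at equal GC content) and GC content less closely (rho 0.375, others -0.462 to 0.168; 0.275 at equal length), so a length-dependent loss of RNA is a candidate explanation. Of 312 genes matched to Taf1 for length, GC content and level, 29.2% lay as far down in this library, so its low Taf1 may come from the same bias, and a knockdown in this animal stays open and untested.

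Cholinergic genes were lower in N than in control mice. The list median was -0.2313 in the Ambn class where it was nearer 0 and -0.4951 in the other, and camera with the preset correlation called it in both. The decrease was thus seen within either class. No exact test of scores was run within a class, so the Ambn class is not taken as excluded. The cholinergic score minus the spiny neuron score was lower in N by -0.159 (exact permutation p = 0.0155, not adjusted), so cholinergic genes fell further than spiny neuron genes. This cannot decide on dilution by RNA of another tissue, since such tissue may itself hold transcripts of the spiny neuron list. An effect of the N miRNA, a difference in the piece of striatum taken and differences between litters stay open and were not tested. The CN group, which targets the same form, had a score difference of -0.096 from the controls (exact permutation p = 0.0303, adjusted p = 0.235).

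Endothelial and mural genes were lower in N as well, with a median of -0.3205 in the Ambn class where it was nearer 0 and -0.3546 in the other. The decrease was thus of similar size within either class. No exact test of scores was run there, and the Ambn class is not taken as excluded. The endothelial and mural score minus the spiny neuron score was lower in N by -0.199 (exact permutation p = 0.0174, not adjusted). For the same reason this cannot decide on dilution by another tissue, which may also hold vessels. How the blood was removed from the tissue is not given in the sources used here, and a vascular difference between the groups stays open and untested.

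A few further values lay far from the rest of their group. Taf1 in N library 4 was at 83.7 CPM (nearest 94.8), the cholinergic score of CN library 3 was 0.05496 and the oligodendrocyte precursor score of control library 8 was 0.08251. In all, 9 of 66 groups of values held such a library, where chance gives about 3.

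The mouse library without a stated injection lay above all 8 controls for red blood cells (2.75, highest control 1.67), cortical and hippocampal excitatory neurons (0.884, 0.675), reactive astrocytes (0.759, 0.343), complement (0.552, 0.186), endothelium and mural cells (0.52, 0.129), activated microglia (0.344, 0.18), lymphocytes and monocytes (0.297, 0.239) and ependymal cells (0.241, 0.202). It lay below them for cholinergic neurons (-0.146, lowest control -0.0705) and oligodendrocyte precursors (-0.0449, -0.029). It lay above for 8 lists and below for 2 of 36, where 8 outside the range are given by chance.

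Each comparison was refitted on 100 splits of its libraries, the real one included. For genes called, 100 of 100 splits gave at least the real count of 0 in all 6 comparisons, which no split can miss, and the highest other split gave 6, 39 and 64 genes in mouse (CN against control, N against control, CN against N) and 1314, 3 and 1 in rat. Without CN library 2, 1 of 100 splits, the real one, reached the 197 genes of N against control (highest other 67). That fit was chosen after seeing the data and the splits do not repeat the choice, so chance is not taken as excluded. In the same fit 3 of 100 splits reached the 70 genes of CN against N (highest other 954). Chance is not taken as excluded there either, since the share lies near 0.05 and the draw depends on the order of the libraries. For genes at an unadjusted p under 0.05 in mouse, 1 of 100 splits reached the 1822 of N against control (highest other 1744), 30 the 1623 of CN against control (3759) and 27 the 2294 of CN against N (4766). The medians over other splits were 367, 876 and 1312 in this order, and for CN against control, N against control and CN against N in rat 468, 705 and 573. In rat 14 splits reached the 1442 of CN against control (highest other 4173), 62 the 634 of N against control (3071) and 12 the 1123 of CN against N (2722). For N against control in mouse no other split drawn reached the real count. The nearest lay close to it (1744), and the draw depends on the order of the libraries. Chance is therefore not taken as excluded for any of these counts at an unadjusted p. For lists called by camera, 30 splits reached the 10 of CN against control, 2 the 15 of N against control and 28 the 12 of CN against N, each with a highest other of 17 and a median over other splits of 9. For N against control another draw of splits, taken with the libraries in a different order, put the share above 0.05, so chance is not taken as excluded for the number of lists in any of the 3 comparisons. The split with 954 genes beside the real 70 points to differences between libraries other than the injected miRNA, whose nature was not tested.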

How the results depend on the processing

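The Ambn settings, the joint settings with CN library 2 (CN libraries 1 and 2 left out among them), the rat number range and the exact test of list scores were chosen after seeing the data. No paired analysis was possible because the labels give the groups no shared replicate numbers. Planned comparisons of mouse with rat, rat gene lists and the rat sex class were not run. In all settings below the cause of a change was not tested, except where a library left out shows it. The first surrogate variable in mouse was 0.906 in CN library 2, while the others ran from -0.328 (CN library 1) to 0.086 (N library 4). It thus mainly marks CN library 2, and its counts are not independent of leaving that library out.

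The number of genes called for N against control was 209 (74 higher) with only the 2 groups compared, 214 (97 higher) with the first surrogate variable, 73 (27 higher) with DESeq2, 16 without CN library 2 and with the Ambn class as a covariate, 324 (108 higher) without CN library 2 and with the sex class, 45 (14 higher) without CN library 2 and the 3 choroid-rich N libraries, and 300 (107 higher) without CN libraries 1 and 2. It was 0 with RLE, limma-voom, no filter, a stricter filter, the sex class or the Ambn class alone, and within either Ambn class. For CN against N it was 8 with no filter, 424 (172 higher) with the surrogate variable, 162 (78 higher) with DESeq2, 8 without CN library 2 with the Ambn class and 4 (2 higher) without CN libraries 1 and 2. In rat, DESeq2 called 32 (4 higher) for CN against control and 1 (0 higher) for N against control. Leaving out each library in turn, the counts ran from 0 to 1 (without CN library 1) for CN against control, 0 to 197 (without CN library 2) for N against control, 0 to 70 (without CN library 2) for CN against N and 0 to 3 (without control library 1) for rat CN against control.

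The number of lists called was 0, 1 and 0 (CN against control, N against control, CN against N) with an estimated correlation, 0, 0 and 0 with it and without CN library 2, and 0, 9 (3 higher) and 0 by the exact test of scores. For N against control it was 9 with a stricter filter and 7 with the surrogate variable, and for CN against control 6 without CN library 2 and with the Ambn class. With each library left out it ran from 6 (CN library 2) to 12 for CN against control, from 9 (CN library 1) to 18 for N against control and from 8 (CN library 2) to 15 for CN against N.

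Taf1 changed sign for N against control with the surrogate variable (0.032) and among libraries with Ambn (0.022), and without CN library 2 with the Ambn class for CN against control (0.036) and CN against N (0.056). It was 0.030 and 0.046 for these without CN libraries 1 and 2. Leaving out each library, it ran from -0.18 to 0.035 for CN against control, -0.045 to 0.0093 for N against control and -0.16 to 0.051 for CN against N, the highest values of CN coming without CN library 2 and that of N without N library 4. Ly6e for CN against control was at 0.040 with the sex class and 0.070 among libraries with Ambn (-0.35 to 0.097 with each library left out), Unc79 at -0.034 with limma-voom (-0.057 to 0.20), and Sik2 for CN against N at -0.20 with limma-voom.

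Among libraries with Ambn camera's direction turned for channels (0.0046), oligodendrocytes (0.021) and ependymal cells (0.080, a median still above 0) for N against control, while the choroid plexus median (-0.14) turned and camera's direction did not. Among those without, where CN has only library 3, they were choroid plexus (-1.43), ependymal cells (-0.15) and neurogenesis (-0.16) for CN against control, cortical excitatory neurons (-0.17) for N against control, and channels (0.059), interferon response (-0.64), the unfolded protein response (-0.034) and ribosomal proteins (-0.045) for CN against N. Without CN library 2 and with the Ambn class, oxidative phosphorylation (-0.045) and ribosomal proteins (-0.038) turned for CN against control and channels (0.038) and ribosomal proteins (-0.077) for CN against N, and without that library alone (with an estimated correlation, which leaves medians as they are) the same lists were at -0.051, -0.045, 0.056 and -0.10. Without CN libraries 1 and 2, channels (0.036), ribosomal proteins (-0.063) and camera's direction for interferon response (0.077) turned for CN against N. Without CN library 2 and the choroid-rich N libraries, oligodendrocytes (0.00094) and choroid plexus (-1.43) turned for N against control. With each library left out, ribosomal proteins ran from -0.045 to 0.45 for CN against control and -0.10 to 0.38 for CN against N, oxidative phosphorylation from -0.051 to 0.39 for CN against control and channels from -0.13 to 0.056 for CN against N.

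With each library left out, the cholinergic median of N against control stayed between -0.47 and -0.34 and the endothelial median between -0.39 and -0.31. Camera with the preset correlation called both lists in each of these refits. With an estimated correlation neither was called without CN library 2 (adjusted p = 0.291 and 0.209 by camera). The exact test of scores was not rerun with N or control libraries left out.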

Other observations

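Several lists showed no call by camera in any mouse comparison with all libraries. Complement genes were called downwards for CN against control without CN library 2 (median -0.17, 0 of 13 passing, adjusted p = 0.876 with an estimated correlation). The subunits of TFIID other than Taf1, the complex that Taf1 organises, had medians of 0.049 for CN against control, -0.015 for N against control and 0.044 for CN against N, with 0 of 17 members passing in each. Medians for N against control were -0.038 for indirect-pathway neurons, where Drd2 (-0.21) fell over the list alone, 0.033 for GABA receptors and synthesis, 0.014 for presynaptic genes and 0.044 for astrocytes, where the gap junction gene Gja1 (0.25) and Aldh1l1 (0.22) rose over the list alone. They were -0.16 for reactive astrocytes, 0.031 for activated microglia, -0.035 for thalamic, septal and pallidal neurons with Lef1 (-0.54) lower, -0.055 for the 3 lymphocyte and monocyte genes, 0.034 for red blood cells, -0.045 for MHC class I, -0.074 for complement, -0.0017 for p53 targets with Zmat3 (-0.34) lower, -0.041 for mitochondrially encoded genes with mt-Nd3 (2.48) higher (not passing without CN library 2) and 0.16 for genes of the sex chromosomes.

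Skeletal muscle transcripts were found in 2 N libraries, with Myh4 at 16.1 CPM in library 5 and 15.7 CPM in library 8. The Xist class held 2 of 8 control, 1 of 8 N and 0 of 5 CN mice. The mouse library without a stated injection had Taf1 at 104 CPM, Ambn at 1.1, and the highest levels of the acute-phase gene Lcn2 (12.6 CPM) and the neutrophil genes S100a8 (5.81) and Ngp (5.5) among the mouse libraries.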
